A study of Homo sapiens with 9 samples.

How the data were processed

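Total RNA from PANC-1 cells was sequenced after 12 h of hypoxia in medium with rakicidin A, BE-43547A1 or DMSO, in 3 libraries per group. Per the labels' protocols, RNA was extracted with a column kit and paired-end libraries with reads of 76 bases were run on an Illumina NextSeq. Per the submitters' processing notes, TopHat2 and HTSeq were used and the builds GRCh37 and hg19 were named. Their versions, settings, order and strand setting are not given in the sources used here. The deposited table holds a count of reads or fragments per annotated feature and library, with no normalization. Its features come from several catalogues, mainly GENCODE and MiTranscriptome. Coordinates are not printed, because the annotation at hand is for GRCh38 (GENCODE v29).

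The 5 summary entries that name no gene were set aside. Relative to the counts on features plus these entries, reads on no feature made up 20.3 to 20.8% in DMSO, 16.4 to 18.0% after rakicidin A and 18.1 to 19.2% after BE-43547A1. Reads placed at more than 1 site made up 19.1 to 22.4% and ambiguous reads 2.65 to 2.94% over all libraries. Counts on features came to 28634532, 27696394 and 30596594 in DMSO, 30634302, 34870860 and 26203326 after rakicidin A and 45048999, 41896682 and 39807220 after BE-43547A1.

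Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features with enough counts by filterByExpr were kept, library sizes were scaled by TMM (factors 1.145 to 1.152 in DMSO, 0.890 to 0.899 after rakicidin A and 0.963 to 0.989 after BE-43547A1), and a quasi-likelihood model with 1 mean per group was fitted to the 9 libraries (6 residual degrees of freedom). The 3 contrasts were each compound against DMSO and rakicidin A against BE-43547A1. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. CPM values are scaled by TMM, and log CPM uses a prior count of 2. Standard errors were taken as the size of the log2 fold change over the square root of the F statistic, and intervals are at 95%. Ratios for genes with 1 to 3 DMSO counts carry an exact interval that covers counting error only, since PCR copies were not marked by molecular identifiers.

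The comparisons, tests, lists, naming rule and alternatives were set before the data were examined. Named genes were, for each compound against DMSO, the 10 largest rises and 10 largest falls among genes that passed with a mean CPM of at least 2 and no overlap of log CPM between the groups, and 6 in each direction for the direct comparison. For each list up to 4 members with the smallest product of the unadjusted p of the compounds were named. Features without a symbol, ribosomal RNA and loci with clone names were passed over. Some genes that the rule or a list would name are not reported here. Of 29 fixed lists with 737 entries, 736 were matched and 679 measured, and the 27 lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Camera asks whether a list moves more than the other genes. The alternative fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes.

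Alternatives were RLE size factors, total counts alone, no filter, DESeq2 1.42.0, limma-voom, the 6 libraries of a comparison, the replicate number as a block, mitochondrial and ribosomal RNA genes left out, a log2 fold change of at least 1, each library left out, and for lists an estimated correlation and fry. Thinning of all libraries to 26203326 counts was added after seeing the data. For the overlap of the compounds, all 9 libraries, DMSO included, were simulated 20 times from 1 mean per gene, with no group changed. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

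The pipeline was tested on simulated data with known changes, 3 libraries per group. It recovered 74.6, 79.1 and 80.6% of genes changed 1.5-fold in 3 runs, 95.5, 100 and 100% of those changed 2-fold, and 100% of those changed 4-fold. False calls made up 5.66, 8.30 and 8.19% of the calls, above the nominal 5% in all 3 runs. In all 3 runs camera called a list of 30 moved genes and did not call a list of 30 unchanged genes. The simulated genes varied independently and few were changed, so this does not test the preset correlation on the real lists.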

Results

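PANC-1 cells, an established human line from a pancreatic carcinoma, were kept under hypoxia for 12 h before their total RNA was sequenced. The medium held rakicidin A (42 nM), a cyclic lipodepsipeptide of bacterial origin, BE-43547A1 (41 nM) or the solvent DMSO (0.04%), with 3 libraries per group. The doses of the compounds differed slightly. The DMSO content of the medium with a compound is not given in the labels, so whether the solvent was matched is not known. No library came from cells in normal oxygen, so every comparison was made within hypoxia. The DMSO libraries held 27696394 to 30596594 counts on annotated features, the rakicidin A libraries 26203326 to 34870860 and the BE-43547A1 libraries 39807220 to 45048999. Of these features, called genes here, 22353 had enough counts to be tested. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

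The first principal component of log CPM held 69.8% of the variance and placed the DMSO libraries at -105.8 to -101.9 and the treated libraries at 36.7 to 66.4. The second held 16.1% and placed rakicidin A at -53.3 to -43.05 and BE-43547A1 at 31.4 to 43.5. On the second component replicate 3 lay apart after rakicidin A (-53.3, others -43.8 and -43.05) and after BE-43547A1 (31.4, others 43.5 and 43.4). DMSO replicate 3 stood apart from its group in the transcripts that follow. MALAT1, an abundant nuclear long noncoding RNA looked up after the libraries were compared, reached 8863 CPM in it against 4915 and 4994 in the other DMSO libraries. It lay at 6646 to 7273 CPM after rakicidin A, within the DMSO range, and at 10350 to 11670 CPM after BE-43547A1, above it. Mitochondrially encoded transcripts took 0.520% of its counts, against 0.287% and 0.334%. The library was kept, and without it 14648, 16253 and 11456 genes passed in the 3 comparisons, against 14455, 15738 and 10423 with it.

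The first comparison asked which transcripts changed with rakicidin A under hypoxia. Genes of the stress response of the endoplasmic reticulum (ER), of the integrated stress response and of inflammation rose. Genes of mitosis fell, a list call lost with an estimated correlation (camera adjusted p = 0.0947). ATF3, a stress-induced transcription factor, rose from 11.7 ± 0.824 to 942 ± 38.4 CPM (mean ± SD, n = 3 libraries), a log2 fold change of 6.34 ± 0.08 (± SE, edgeR adjusted p = 2.32e-20). HERPUD1, which serves the breakdown of misfolded ER proteins, rose from 17.5 ± 1.29 to 834 ± 24.6 CPM (5.57 ± 0.07, adjusted p = 2.41e-20), and RCAN1, an inhibitor of the phosphatase calcineurin, from 20.2 ± 0.942 to 1213 ± 22.1 CPM (5.91 ± 0.06, adjusted p = 3.39e-21). DGAT2, an enzyme of triglyceride synthesis, fell from 15.9 ± 0.867 to 0.524 ± 0.259 CPM (-4.98 ± 0.21, adjusted p = 2.21e-13), and ID1, a target of BMP signalling, from 269.6 ± 43.5 to 24.2 ± 1.71 CPM (-3.48 ± 0.11, adjusted p = 2.55e-15).

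Among the 10 largest rises were also DUSP8, a phosphatase of MAP kinases (6.16 ± 0.19), CCL20, a chemokine (5.59 ± 0.16), IL1RL1, the receptor of interleukin 33 (4.79 ± 0.08), and the pseudogene ZSCAN12P1 (4.97 ± 0.18), whose reads may belong in part to its parent gene. The remaining rises were of genes almost absent from the DMSO libraries, for which a ratio with its 95% counting interval replaces the fitted change. KRTAP2-3, a keratin-associated gene with close copies, had 1 count over the DMSO libraries and a ratio of 440.6 (78.6 to 17450). MMP10, a secreted matrix protease, had 3 counts and a ratio of 122.6 (41.6 to 597.7), and the antisense transcript KRTAP5-AS1 had 3 counts and a ratio of 37.6 (12.5 to 185.8). The 10 largest falls also took in the noncoding RNA LINC00461 (-3.55 ± 0.14), the transporter gene SLC16A14 (-3.39 ± 0.19), the secreted protease gene ADAMTS15 (-3.36 ± 0.12) and the protocadherin gene PCDH18 (-3.24 ± 0.18). FRAT1, a part of Wnt signalling (-3.17 ± 0.20), PAQR8 (-3.06 ± 0.18), the homeobox gene HOXB8 (-3.02 ± 0.19) and KLHL14 (-3.01 ± 0.11) completed them. In all, 14455 genes passed, 7141 higher and 7314 lower, and 6211 of them changed by at least 1 on the log2 scale. Scaled by total counts alone, 4480 were higher and 11380 lower, since the median of all genes moved by -0.356, so the sign of a small change is relative to that median.

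Of 27 fixed lists, 8 rose and 3 fell by camera, which compares a list with all other genes. Square brackets after a list give how many members were higher and lower with total counts alone, which moved most lists downward. All 23 measured genes of ER chaperones and the unfolded protein response rose (median log2 2.54, [23, 0], camera adjusted p = 8.66e-72). DNAJB9, an ER cochaperone, rose from 26.8 ± 2.11 to 672 ± 18.9 CPM. MANF, a secreted ER stress protein (4.02 ± 0.07), and XBP1, a transcription factor of this response (3.09 ± 0.06), rose as well. Of 41 genes of ATF4 and the integrated stress response, 37 rose and 2, ATF5 and VLDLR, fell (median 1.40, [33, 4], adjusted p = 2.25e-41). DDIT3, which encodes CHOP, rose from 16.98 ± 1.36 to 398 ± 14.0 CPM, and SESN2 (3.99 ± 0.06) and PPP1R15A (3.68 ± 0.07) rose with it. All 23 genes of the NF-kB list rose (median 2.15, [22, 0], adjusted p = 1.99e-33). The neutrophil chemokine IL8 rose from 11.8 ± 0.201 to 316 ± 21.8 CPM, and so did the cytokines IL11 (4.01 ± 0.12) and LIF (2.77 ± 0.07) and the superoxide dismutase SOD2 (2.73 ± 0.05). These 3 calls held with an estimated correlation between genes (adjusted p = 0.00548, 0.00787 and 0.0200), and the calls of the other 8 lists did not.

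Immediate early genes, which cells switch on first after a stimulus, rose in 17 of 22 cases (median 1.53, [16, 4], adjusted p = 2.51e-14, and adjusted p = 0.114 with an estimated correlation). DUSP5 rose from 28.2 ± 1.21 to 567 ± 16.5 CPM, DUSP1 (2.71 ± 0.06), KLF4 (2.79 ± 0.08) and JUN (2.05 ± 0.07) rose, and FOS, JUNB and ZFP36 fell. EGR1 did not pass (0.088, adjusted p = 0.716), but rose by 0.50 (adjusted p = 0.00223) without DMSO replicate 3, the highest of the values with 1 library left out (lowest -0.075). The lysosome and autophagy list rose in 15 of 26 genes (median 0.39, [11, 10], adjusted p = 1.91e-05, and adjusted p = 0.240 with an estimated correlation). The autophagy receptor SQSTM1 (2.06 ± 0.06), WIPI1 (2.67 ± 0.08) and MAP1LC3B (2.58 ± 0.10) rose, while CTSD fell. This list (11 up, 10 down, median 0.035), the p53 list (10 and 10, 0.044) and the ribosome biogenesis list (11 and 10, 0.015) had about as many lower as higher genes with total counts alone. Among p53 targets, 12 rose and 6 of 22 fell (median 0.40, [10, 10], adjusted p = 0.000188, and adjusted p = 0.0537 with an estimated correlation). GADD45A, a gene of growth arrest, rose from 39.4 ± 2.31 to 745 ± 20.4 CPM, and AEN (2.85 ± 0.06), the death receptor gene TNFRSF10B (2.20 ± 0.06) and BBC3, which encodes PUMA (1.83 ± 0.13), rose too. The list of the BCL2 family and death receptors rose in 12 and fell in 6 of 22 genes (median 0.53, [10, 9], adjusted p = 0.00663, and adjusted p = 0.463 with an estimated correlation). Its members include PMAIP1, which encodes NOXA (2.78 ± 0.08), BCL2A1 (3.44 ± 0.10), BIRC2 (1.78 ± 0.07) and the survival gene MCL1 (0.98 ± 0.05). Ribosome biogenesis genes rose in 15 of 25 cases (median 0.37, [11, 10], adjusted p = 0.00522, and adjusted p = 0.463 with an estimated correlation). GNL3 (1.53 ± 0.06), RRP12 (1.53 ± 0.05), WDR43 (1.45 ± 0.06) and DDX21 (1.17 ± 0.05) rose, while NOP56, WDR12 and RRS1 fell.

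Mitosis genes fell in 26 of 28 cases (median -0.88, [1, 26], adjusted p = 9.14e-14, and adjusted p = 0.0947 with an estimated correlation), and UBE2C and ECT2 rose. KIF20A, a motor of cytokinesis, fell from 126 ± 3.60 to 23 ± 2.33 CPM, followed by the checkpoint kinase gene BUB1B (-1.54 ± 0.06), the topoisomerase gene TOP2A (-1.51 ± 0.06) and ASPM (-1.40 ± 0.06). The list of DNA replication and the G1/S transition fell in 18 of 27 genes (median -0.38, [1, 24], adjusted p = 0.0408, and adjusted p = 0.463 with an estimated correlation). RRM2 (-0.81 ± 0.06) and PCNA (-0.66 ± 0.06) fell. This call was lost without rakicidin A replicate 3 (adjusted p = 0.0568) and without BE-43547A1 replicate 1, 2 or 3 (0.0559, 0.05002 and 0.0537). CDC6, which loads the replicative helicase, went against the list and rose from 97.6 ± 4.29 to 537 ± 16.4 CPM (2.46 ± 0.07, adjusted p = 3.35e-16), and MCM7 and FEN1 rose as well.

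Nuclear genes of oxidative phosphorylation fell in 45 of 68 cases (median -0.30, [1, 64], adjusted p = 0.00203, and adjusted p = 0.584 with an estimated correlation). ATP5G2 of the ATP synthase (-0.69 ± 0.08) and UQCRFS1 of complex III (-0.34 ± 0.07) fell. Cytochrome c, CYCS, rose alone (0.70 ± 0.07). Among the 13 mitochondrially encoded genes 0 rose and 8 fell, and the list did not pass ([0, 11], adjusted p = 0.327). DMSO replicate 3 carried much of this fall, with a list score of 0.38 against -0.33 and -0.049 in the other DMSO libraries and -0.40 to -0.22 after rakicidin A. Without it 2 rose and 5 fell, and 5 fell without rakicidin A replicate 1 or 2. MT-ND4 fell from 400.4 ± 66.2 to 291 ± 8.58 CPM (-0.46 ± 0.11, adjusted p = 0.00121). MT-ND3 fell by 0.59, but not without DMSO replicate 3 (-0.16, adjusted p = 0.253) or rakicidin A replicate 2 (-0.44, 0.109). MT-CO3 also fell (-0.70 ± 0.20, adjusted p = 0.00477), and MT-ND6 did (-0.42 ± 0.12, adjusted p = 0.00537) except without DMSO replicate 2 (-0.22, 0.0559). DESeq2 passed none of MT-ND3, MT-CO3 and MT-ND6 (adjusted p = 0.215, 0.111 and 0.0991). The mitochondrial ribosome list (3 up, 15 down, 16 not passing, [1, 30], adjusted p = 0.282) held a lower MRPL16 (-0.89 ± 0.08) and MRPS27 (-0.49 ± 0.06) and a higher MRPL15 (0.77 ± 0.06). In the tricarboxylic acid cycle, where 19 genes fell with total counts alone (5 up, 7 down, 10 not passing, [1, 19], adjusted p = 0.836) pyruvate carboxylase, PC, rose (1.81 ± 0.09) and PDHB fell (-0.39 ± 0.06). Regulators of mitochondrial biogenesis split (6 up, 5 down, 4 not passing, [3, 9], adjusted p = 0.920), with TFB2M higher (1.46 ± 0.07) and PPARGC1B lower (-1.86 ± 0.12). So did mitochondrial chaperones and proteases (9 up, 4 down, 5 not passing, [6, 9], adjusted p = 0.114), with TIMM17A of the import channel (1.86 ± 0.07) and the chaperone HSPA9 (1.23 ± 0.06) higher and SPG7 lower (-0.64 ± 0.06). Genes of mitochondrial dynamics split as well (6 up, 5 down, 4 not passing, [4, 9], adjusted p = 0.744). CALCOCO2 was higher (0.76 ± 0.06) and MIEF2 lower (-1.58 ± 0.17).

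Targets of the hypoxia factor HIF went both ways, 18 up and 13 down of 32 (median 0.23, mean -0.11, [11, 16], adjusted p = 0.955). KDM3A rose (1.04 ± 0.06) while PPFIA4 (-1.66 ± 0.08), HILPDA (-1.44 ± 0.08) and MXI1 (-1.26 ± 0.08) fell. The well known targets VEGFA (0.95 ± 0.06) and ADM (1.34 ± 0.06), picked after their values were seen, rose. In glycolysis 13 genes fell, as ALDOC did (-2.05 ± 0.11). HK2 rose from 58.4 ± 7.63 to 229.7 ± 8.49 CPM, and PFKFB3 (1.40 ± 0.07), the glucose transporter SLC2A1 (0.67 ± 0.06), ENO1 and PDK1 rose ([4, 19], list adjusted p = 0.448). Heat shock genes fell in 12 of 18 cases without passing as a list ([2, 15], adjusted p = 0.0616, but 0.0341 without DMSO replicate 1 and 0.0416 with the replicate number as a block). HSPA8, the constitutive cytosolic chaperone, fell from 3257 ± 251 to 1043 ± 43.8 CPM, HSPA4L fell (-0.54 ± 0.05) and DNAJB1 rose (0.60 ± 0.07). NRF2 targets (9 up, 4 down of 19, [5, 9], adjusted p = 0.0847) held higher HMOX1, the heme oxygenase gene (1.22 ± 0.06), TXNRD1 (1.47 ± 0.06) and OSGIN1 (2.61 ± 0.13). Cholesterol synthesis (11 up, 7 down of 24, [9, 13], adjusted p = 0.0798) passed without DMSO replicate 1 (0.0341) or rakicidin A replicate 2 (0.0488). HMGCS1 (1.32 ± 0.06) and STARD4 (1.96 ± 0.07) were higher.

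Fatty acid synthesis genes were mixed (4 up, 6 down of 14, [2, 10], adjusted p = 0.951), with LPIN1 (1.24 ± 0.06) and MID1IP1 (1.02 ± 0.09) higher and PNPLA3 lower (-1.08 ± 0.18). Interferon genes were mixed too (5 up, 6 down of 20, [2, 12], adjusted p = 0.448), with SAMD9 (-2.71 ± 0.11) and IFIT1 (-1.11 ± 0.10) lower and IFIT2 higher (0.95 ± 0.08). Stem cell and mesenchymal genes (8 up, 7 down of 20, median -0.043, mean 0.15, [3, 12], adjusted p = 0.962) held higher ZEB1 (0.83 ± 0.06) and CXCR4 (1.45 ± 0.15) and a lower KRT8 (-0.26 ± 0.05). The list so named also holds epithelial genes, KRT8 and CDH1 among them, so its direction does not mark a cell state. Under TMM most cytosolic ribosomal proteins, 32 of 45, did not pass, whereas 41 fell with total counts alone (5 up, 8 down, [0, 41], adjusted p = 0.566). The number that fell was 5 without DMSO replicate 2, 13 without DMSO replicate 3 and 4, 4 and 3 without rakicidin A replicate 1, 2 and 3. RPL28 rose by 0.53 and RPL12 by 0.27, the latter lost without DMSO replicate 1 (adjusted p = 0.0693), rakicidin A replicate 1 (0.0940) or rakicidin A replicate 2 (0.0555) and turned to -0.084 by total counts alone. Histone genes (10 up, 1 down of 13, [1, 3], adjusted p = 0.429) included a higher HIST2H2BE (0.82 ± 0.07) and a lower HIST1H1D (-0.74 ± 0.09). Too few leukocyte and stromal markers were measured to test. CD14 and ITGAM, of leukocytes, did not pass. Among stromal markers COL1A1 fell from 7.29 ± 2.09 to 3.39 ± 0.594 CPM and THY1 fell (-0.52 ± 0.17, lost without rakicidin A replicate 1, -0.43, adjusted p = 0.0561). With total counts alone the medians of 6 lists that had been above 0 turned negative: mitochondrial chaperones (-0.14), mitochondrial dynamics (-0.27), HIF targets (-0.12), NRF2 targets (-0.13), cholesterol synthesis (-0.22) and histones (-0.013). Where 5 or fewer genes went 1 way, here and in the other comparisons, those that can be reported are named, after their values were seen. Higher were PDHX, PC, IDH3G and FH of the tricarboxylic acid cycle, MRPL15, MRPS18A and DAP3 of the mitochondrial ribosome, DNAJB1, BAG3, HSPA4 and STIP1 of heat shock. So were FASN, ELOVL5, LPIN1 and MID1IP1 of fatty acid synthesis, IFIT2, MX1, IRF7, IFIH1 and HERC5 of interferon, and RPL4, RPL12, RPL19, RPL28 and RPS9 of the ribosome. Many of these rises, and those of ENO1, MCM7, FEN1 and ECT2, rest on the scaling. With total counts alone PDHX (-0.20), FH (-0.17), DAP3 (-0.14), HSPA4 (-0.16), ELOVL5 (-0.21), RPL19 (-0.175), ENO1 (-0.16) and MCM7 (-0.17) fell. IDH3G (-0.025), STIP1 (-0.062), FASN (-0.069), HERC5 (-0.002), RPL4 (-0.12), RPL12 (-0.084), RPS9 (-0.12), FEN1 (-0.051) and ECT2 (-0.049) changed sign without passing, and MRPS18A, MX1, IRF7 and RPL28 no longer passed. Lower were PPARGC1B, TFB1M, POLRMT, TEFM and SLIRP of mitochondrial biogenesis and HSPE1, CLPX, SPG7 and OMA1 of its chaperones. So were FUNDC1, OPA1, MIEF2, PHB2 and FKBP8 of its dynamics, and the NRF2 targets TALDO1, ABCC3, TXN and PRDX1. Adjusted over the list alone, the counts were the same for every list except oxidative phosphorylation (1 up, 46 down), mitochondrial biogenesis (7 and 6), ATF4 (38 and 2) and cytosolic ribosomal proteins (3 and 3).

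The second comparison asked the same of BE-43547A1. Inflammatory, immediate early and ER stress genes rose and mitosis genes fell. IL11, a cytokine of the interleukin 6 family, rose from 4.12 ± 0.548 to 323 ± 30.1 CPM (mean ± SD, n = 3), a log2 fold change of 6.29 ± 0.12 (edgeR adjusted p = 3.69e-18). ATF3 reached 1007 ± 66.2 CPM (6.43 ± 0.08, adjusted p = 1.88e-20) and RCAN1 1144 ± 11.2 CPM (5.83 ± 0.06, adjusted p = 4.10e-21). SKP2, a subunit of the ubiquitin ligase that removes inhibitors of cell division, fell from 32.2 ± 0.580 to 3.06 ± 0.365 CPM (-3.39 ± 0.09, adjusted p = 5.41e-16), and DGAT2 fell to 0.756 ± 0.240 CPM (-4.38 ± 0.18, adjusted p = 1.54e-13).

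The 10 largest rises further held SEMA4A, a semaphorin with 7 counts over the DMSO libraries (7.66 ± 0.28), DUSP8 (7.15 ± 0.18), CCL20 (6.78 ± 0.15) and ZSCAN12P1 (5.69 ± 0.17). Against the 1 to 3 DMSO counts of the rest, the ratios were 421.9 for KRTAP2-3 (95% counting interval 75.4 to 16700), 228.2 for KRTAP5-AS1 (77.8 to 1109) and 108 for MMP10 (36.7 to 526.1). Besides DGAT2 and SKP2, the 10 largest falls were of PCDH18 (-3.69 ± 0.18), KLHL14 (-3.41 ± 0.11), the zinc finger genes ZNF737 (-3.37 ± 0.13) and ZNF681 (-3.05 ± 0.16), LINC00461 (-3.19 ± 0.12), SLC16A14 (-3.14 ± 0.17), the helicase gene PIF1 (-3.09 ± 0.10) and PSRC1, a gene of the mitotic spindle (-3.01 ± 0.10). In all, 15738 genes passed, 7898 higher and 7840 lower, and 7075 of them changed by at least 1 on the log2 scale. Scaled by total counts alone, 5951 were higher and 10450 lower, with the median of all genes moved by -0.237.

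By camera, 7 of the 27 lists rose and 3 fell, and 6 of these calls held with an estimated correlation. Square brackets again hold the numbers higher and lower with total counts alone. All 23 NF-kB genes rose (median 2.63, [23, 0], adjusted p = 3.49e-50), with IL8 at 569.9 ± 52.7 CPM (5.59 ± 0.08), LIF (3.11 ± 0.07) and SOD2 (2.88 ± 0.05). All 22 immediate early genes rose (median 2.08, [22, 0], adjusted p = 1.79e-29). JUN went from 158 ± 5.62 to 1984 ± 212 CPM, and DUSP5 (3.88 ± 0.06), KLF4 (3.65 ± 0.08) and DUSP1 (2.62 ± 0.06) followed. All 23 ER chaperone genes rose (median 1.85, [22, 0], adjusted p = 1.13e-42), as HERPUD1 (5.08 ± 0.07), DNAJB9 (3.79 ± 0.08), MANF (3.48 ± 0.07) and XBP1 (2.91 ± 0.06) did. The ATF4 list rose in 36 of 41 genes (median 1.06, [28, 4], adjusted p = 6.88e-25), with DDIT3 (4.42 ± 0.07), SESN2 (3.81 ± 0.06) and PPP1R15A (3.61 ± 0.07), while ATF5, PSPH and VLDLR fell. Among p53 targets 12 rose, 5 fell and 5 did not pass (median 0.37, [11, 8], adjusted p = 5.84e-05). GADD45A at 752 ± 23.7 CPM (4.26 ± 0.06), AEN (2.59 ± 0.06) and TNFRSF10B (1.66 ± 0.06) were up and SESN1, RRM2B, XPC, TP53I3 and CCNG1 were down. Mitosis genes fell in 27 of 28 cases (median -1.23, [1, 27], adjusted p = 7.45e-21). KIF20A at 16.8 ± 1.56 CPM (-2.90 ± 0.08), ASPM (-1.97 ± 0.06), BUB1B (-1.90 ± 0.06) and TOP2A (-1.67 ± 0.06) fell, and UBE2C rose. With an estimated correlation these 6 lists gave adjusted p = 0.0132, 0.0285, 0.0132, 0.0204, 0.0285 and 0.0285 in that order.

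The lysosome and autophagy list rose in 21 of 26 genes with 0 falls (median 0.82, [17, 4], adjusted p = 2.10e-09, and adjusted p = 0.0984 with an estimated correlation). SQSTM1 reached 1819 ± 117 CPM (2.33 ± 0.06), and MAP1LC3B (2.56 ± 0.10), the sialidase gene NEU1 (2.23 ± 0.07) and WIPI1 (1.65 ± 0.08) rose. Cholesterol synthesis rose in 20 of 24 genes (median 0.40, [11, 3], adjusted p = 0.000152, and adjusted p = 0.198 with an estimated correlation). HMGCS1 rose from 114 ± 7.54 to 445 ± 9.36 CPM, and IDI1 (1.10 ± 0.06) rose. DNA replication genes fell in 23 of 27 cases (median -0.53, [1, 25], adjusted p = 5.84e-05, and adjusted p = 0.123 with an estimated correlation). MCM10 (-1.41 ± 0.07), PCNA (-1.05 ± 0.06) and RRM2 (-0.80 ± 0.06) fell, whereas CDC6 rose (0.90 ± 0.06). The mitochondrial ribosome fell in 20 of 34 cases (median -0.28, [1, 28], adjusted p = 0.0221, and adjusted p = 0.602 with an estimated correlation). MRPL16 (-1.26 ± 0.08), MRPS27 (-0.87 ± 0.06) and MRPL20 (-0.58 ± 0.06) fell, and 5 members, MRPL12, MRPL15, MRPL37, MRPS7 and DAP3, rose.

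Oxidative phosphorylation did not pass (9 up, 24 down of 68, [2, 52], adjusted p = 0.344), with UQCRFS1 (-0.72 ± 0.07) lower and CYCS higher (0.50 ± 0.07). Among mitochondrially encoded genes 0 rose and 6 fell ([0, 11], adjusted p = 0.4503). The number that fell was 10 without DMSO replicate 1, 4 without DMSO replicate 2, 3 without DMSO replicate 3, 2 without BE-43547A1 replicate 1 and 3 without BE-43547A1 replicate 3, with 1 rise in each of the last 4. MT-ND4 fell (-0.42 ± 0.11, adjusted p = 0.00221). MT-CO3 fell by 0.53, but not without DMSO replicate 3 (-0.072, adjusted p = 0.459), BE-43547A1 replicate 1 (-0.48, 0.0734) or BE-43547A1 replicate 3 (-0.45, 0.0918). Other lists of metabolism did not pass. The tricarboxylic acid cycle (3 up, 14 down, [2, 19], adjusted p = 0.361) had PC up (1.78 ± 0.09) and PDHB down (-0.79 ± 0.06). Glycolysis (8 up, 7 down, [5, 14], 0.796) had HK2 (1.97 ± 0.08) and PFKFB3 (1.82 ± 0.07) up and ALDOC down (-1.47 ± 0.10). Fatty acid synthesis (4 up, 2 down, [2, 6], 0.594) had LPIN1 (1.12 ± 0.06) and FASN (0.78 ± 0.09) up. Mitochondrial biogenesis (4 up, 7 down, [2, 10], 0.361), chaperones (7 up, 6 down, [4, 10], 0.796) and dynamics (6 up, 7 down, [4, 8], 0.796) did not pass either. TFB1M (-1.50 ± 0.08) and MIEF2 (-2.07 ± 0.17) were lower and TIMM17A (1.41 ± 0.07) and LONP1 (0.77 ± 0.05) higher. HIF targets fell in 15 and rose in 10 of 32 cases ([9, 20], adjusted p = 0.445), with PPFIA4 (-1.69 ± 0.08) and HILPDA (-1.43 ± 0.07) lower and KDM3A higher (0.88 ± 0.06).

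NRF2 targets (13 up, 1 down of 19, [7, 4], adjusted p = 0.0576) passed without DMSO replicate 1 (0.0444), DMSO replicate 3 (0.0256), rakicidin A replicate 2 (0.0489), rakicidin A replicate 3 (0.0481) or BE-43547A1 replicate 1 (0.0488). OSGIN1 (2.71 ± 0.13) and HMOX1 (1.33 ± 0.06) were higher. Heat shock genes (9 up, 5 down of 18, [6, 8], adjusted p = 0.624) held a higher DNAJB1 (1.35 ± 0.07) and HSPA1A (0.57 ± 0.09), which shares nearly all its sequence with HSPA1B, and a lower HSPA8 (-0.65 ± 0.07). Cytosolic ribosomal proteins (24 up, 5 down of 45, [11, 15], adjusted p = 0.172) passed without DMSO replicate 2 (0.0484), and RPL24 (0.92 ± 0.08) and RPL12 (1.07 ± 0.10) were higher. The BCL2 family (11 up, 7 down of 22, [7, 9], adjusted p = 0.174) held higher PMAIP1 (2.74 ± 0.08), BCL2A1 (3.05 ± 0.10) and MCL1 (1.14 ± 0.05). Stem cell and mesenchymal genes (11 up, 4 down of 20, [6, 7], 0.267) held higher CXCR4 (1.83 ± 0.14), SNAI1 (1.41 ± 0.11) and the epithelial gene KRT8 (0.45 ± 0.05). Ribosome biogenesis (10 up, 8 down of 25, [8, 14], 0.594) held higher RRP12 (1.48 ± 0.05) and WDR43 (0.85 ± 0.06). Interferon genes (2 up, 8 down of 20, [1, 13], 0.104) held lower SAMD9 (-2.69 ± 0.10) and IFIT1 (-2.17 ± 0.10). Histones (9 up, 1 down of 13, [7, 3], 0.254) held a higher HIST1H2BK (1.01 ± 0.07) and a lower HIST1H1D (-1.12 ± 0.09). Of the markers of other cell types, CD14 (12 counts over the DMSO libraries) rose from 0.120 ± 0.0237 to 0.564 ± 0.112 CPM, ITGAM rose (0.67 ± 0.17) and COL1A1 fell (-0.70 ± 0.18). COL3A1 fell (-0.51 ± 0.21), a call lost without DMSO replicate 1 (adjusted p = 0.128), DMSO replicate 2 (0.0557), BE-43547A1 replicate 2 (0.152) or BE-43547A1 replicate 3 (0.068). With total counts alone, medians above 0 turned negative for mitochondrial chaperones (-0.19), glycolysis (-0.20), heat shock (-0.12), fatty acid synthesis (-0.14), stem cell genes (-0.008), ribosomal proteins (-0.036) and ribosome biogenesis (-0.15). The rarer rises were of PC and IDH3G, of PPRC1, TFB2M, C10orf2 and LRPPRC, of FASN, FADS1, FADS2 and LPIN1, and of IRF7 and IFIH1. The call of IFIH1 was lost without DMSO replicate 1 (adjusted p = 0.132), DMSO replicate 2 (0.0984), BE-43547A1 replicate 1 (0.0567) or BE-43547A1 replicate 3 (0.0772), and total counts alone turned it to -0.047. They also turned MRPL37 (-0.061), MRPS7 (-0.026), DAP3 (-0.064), C10orf2 (-0.054), FADS1 (-0.11) and FADS2 (-0.048) without a pass, and MRPL12 and LRPPRC no longer passed. The rarer falls were of HSPA8, HSPA4L, DNAJA1, AHSA1 and CACYBP, of PRDX1, of PNPLA3 and ACSL3, of ALDH1A3, CDH2, CDH1 and TGFBI, and of RPL7, RPS24, RPS25 and RPSA. Adjusted over the list alone, the counts were the same for every list except mitochondrially encoded genes (0 up, 2 down), mitochondrial dynamics (6 and 8), fatty acid synthesis (3 and 2), lysosome and autophagy (22 and 0) and interferon (1 and 8).

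The third comparison asked how far the compounds moved the same genes. Of 22353 genes, 5539 rose and 5844 fell after both compounds, where independent lists of these sizes would share 2523 and 2565. Log2 fold changes of the compounds correlated across genes, which are not independent replicates (Pearson r = 0.869, covariance 1.35). In 20 simulations of all 9 libraries with no group changed, r averaged 0.5001 (0.485 to 0.511), the covariance averaged 0.0270 and at most 1 gene was called in both. The DMSO libraries were simulated too, so the real ones, with replicate 3 apart from the others, were not tested. An r near 0.5 follows from any shared control of like spread. The 3 DMSO libraries are too few to split, so part of the excess in shared genes may come from the shared controls. For 7359 genes (32.9%) the 95% interval of the difference between the compounds lay within 0.5 of 0 on the log2 scale. These took in ATF3 (-0.22 to 0.032), RCAN1 (-0.022 to 0.19), GADD45A (-0.13 to 0.10), HK2 (-0.15 to 0.15) and RRM2 (-0.13 to 0.10).

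**Figure D1:**
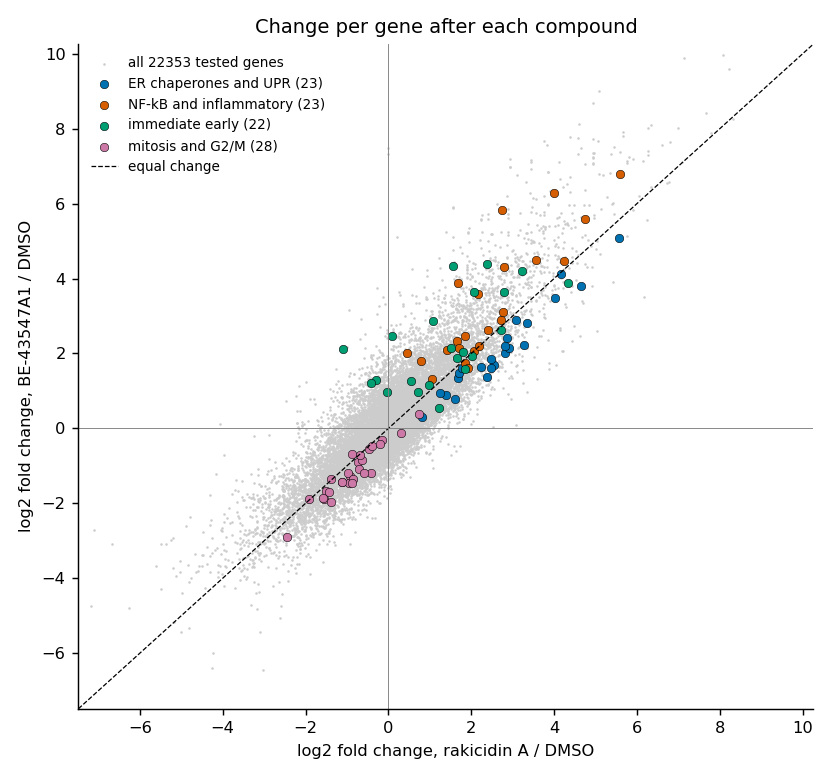
Each point is 1 of 22353 genes, with the log2 fold change of rakicidin A against DMSO on the x axis and that of BE-43547A1 against DMSO on the y axis, both scaled by TMM, and 4 fixed lists in colour. Genes of the ER chaperone list lie in the upper right, and scaling by total counts alone moves the medians of all genes by -0.356 on the x axis and -0.237 on the y axis.

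Tested directly, FOS, EGR1 and IL11 were among the genes higher after BE-43547A1, and RAB39B and ENC1 among those higher after rakicidin A. FOS, a component of the transcription factor AP-1, fell from 25.1 ± 2.46 CPM with DMSO to 11.6 ± 1.48 CPM after rakicidin A and rose to 109.5 ± 19.6 CPM after BE-43547A1 (mean ± SD, n = 3, rakicidin A over BE-43547A1 -3.23 ± 0.12, adjusted p = 1.47e-11). FOSB (-2.78 ± 0.13, adjusted p = 4.13e-11), EGR1 (-2.37 ± 0.19, adjusted p = 1.78e-08), IL11 (-2.28 ± 0.09, adjusted p = 1.66e-11), SEMA4A (-3.91 ± 0.19, adjusted p = 5.43e-11) and KRTAP5-AS1 (-2.60 ± 0.19, adjusted p = 7.32e-09) were also higher after BE-43547A1. RAB39B, a small GTPase of vesicle traffic, rose from 2.17 ± 0.116 to 46.8 ± 4.69 CPM after rakicidin A and to 10.95 ± 0.840 CPM after BE-43547A1 (2.10 ± 0.09, adjusted p = 1.66e-11). ENC1, an actin-binding protein gene, was higher after rakicidin A (1.71 ± 0.07, adjusted p = 1.92e-11), as were SCAND3 (2.14 ± 0.18, adjusted p = 2.84e-08) and the pseudogenes CCDC163P (2.38 ± 0.15), ROCK1P1 (2.18 ± 0.12) and RHOQP3 (1.85 ± 0.19), whose reads may belong in part to their parent genes.

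In the direct test 10423 genes passed, 5387 higher after rakicidin A and 5036 higher after BE-43547A1, and 2167 differed by at least 1 on the log2 scale, 483 and 1684 in these directions. Scaled by total counts alone the split was 3933 and 6862, with the median of all genes moved by -0.119. Of the genes called in the same direction after both compounds, 4970 also differed between them, 2690 with the larger change after BE-43547A1 and 2280 after rakicidin A. The balance differed by direction. Among shared rises 1456 were larger after BE-43547A1 and 1579 after rakicidin A, and among shared falls 1234 and 701. These counts were made under TMM only. The shift of -0.119 with total counts alone favours BE-43547A1 among shared rises and rakicidin A among shared falls. The balance was not recounted with that scaling, so it may rest on TMM.

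By camera 18 of the 27 lists differed, 9 in each direction, but 0 held with an estimated correlation, where 5 lists had an unadjusted p under 0.05 (camera) and fry passed 23. Each of these differences therefore rests on the preset correlation. Square brackets hold the numbers higher and lower after rakicidin A with total counts alone. Higher after rakicidin A were ER chaperones (21 of 23, median 0.55, [19, 0], adjusted p = 1.91e-15, and adjusted p = 0.166 with an estimated correlation), with DNAJB9 (0.85 ± 0.07), MANF (0.55 ± 0.06) and HERPUD1 (0.50 ± 0.06). The ATF4 list was also higher (25 of 41, 0.36, [20, 5], adjusted p = 4.77e-08, and adjusted p = 0.168 with an estimated correlation), and DDIT4 and NUPR1 went the other way. Ribosome biogenesis (17 of 25, 0.30, [15, 2], adjusted p = 1.49e-05, and adjusted p = 0.191 with an estimated correlation) held a higher GNL3 (0.78 ± 0.06). Mitosis (20 of 28, 0.29, [13, 1], adjusted p = 4.15e-05, and adjusted p = 0.238 with an estimated correlation) held a less reduced ASPM (0.58 ± 0.06) and KIF20A (0.46 ± 0.08). DNA replication (13 of 27, 0.19, [11, 5], adjusted p = 0.00026, and adjusted p = 0.191 with an estimated correlation) held a higher CDC6 (1.56 ± 0.06) and MCM10 (0.97 ± 0.07). Of the mitochondrial lists, higher too were chaperones (12 of 18, 0.32, [11, 4], adjusted p = 0.00618, and adjusted p = 0.265 with an estimated correlation) and biogenesis (8 of 15, 0.21, [6, 4], adjusted p = 0.0130, and adjusted p = 0.191 with an estimated correlation). The mitochondrial ribosome was higher (19 of 34, 0.22, [14, 9], adjusted p = 0.0169, and adjusted p = 0.419 with an estimated correlation). TFB1M (0.86 ± 0.08), TFB2M (0.80 ± 0.07) and MRPS27 (0.38 ± 0.06) were examples. So was the BCL2 family (11 of 22, 0.18, [9, 4], adjusted p = 0.0187, and adjusted p = 0.406 with an estimated correlation), with BIRC2 (0.68 ± 0.07). Lower in these lists were FBL, PTTG1, TYMS and UHRF1, HSPE1, TRAP1 and HTRA2, MRPL4, MRPL11, MRPL24, MRPS7 and MRPS15, and BCL2L11, MCL1 and BAD. MCL1 did not pass without rakicidin A replicate 1 (-0.13, adjusted p = 0.0977), rakicidin A replicate 3 (-0.14, 0.0875), BE-43547A1 replicate 2 (-0.16, 0.0566) or BE-43547A1 replicate 3 (-0.14, 0.0643).

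Higher after BE-43547A1 were immediate early genes (16 of 22, median -0.79, [2, 17], adjusted p = 4.88e-14, and adjusted p = 0.168 with an estimated correlation), with JUN (-1.60 ± 0.07) and KLF4 (-0.86 ± 0.06), while DUSP5, DUSP6 and MYC went the other way. So were NF-kB genes (17 of 23, -0.67, [1, 18], adjusted p = 4.60e-14, and adjusted p = 0.166 with an estimated correlation), with IL8 (-0.85 ± 0.07) and LIF (-0.34 ± 0.06), while NFKB1 went the other way. Heat shock genes (12 of 18, -0.33, [0, 12], adjusted p = 1.83e-06, and adjusted p = 0.191 with an estimated correlation) held HSPA8 (-0.995 ± 0.070) and DNAJB1 (-0.75 ± 0.07). Cytosolic ribosomal proteins (27 of 45, -0.27, [0, 38], adjusted p = 1.34e-05, and adjusted p = 0.265 with an estimated correlation) held RPL24 (-0.95 ± 0.08) and RPL12 (-0.80 ± 0.10). Also higher after BE-43547A1 were oxidative phosphorylation (36 of 68, -0.21, [3, 46], adjusted p = 0.00026, and adjusted p = 0.370 with an estimated correlation) and cholesterol synthesis (14 of 24, -0.28, [1, 16], adjusted p = 0.000261, and adjusted p = 0.238 with an estimated correlation) with HMGCS1 (-0.65 ± 0.06). The lysosome list was higher too (16 of 26, -0.32, [3, 19], adjusted p = 0.00187, and adjusted p = 0.265 with an estimated correlation) with NEU1 (-0.78 ± 0.07), although WIPI1 was lower (1.02 ± 0.07). The same held for stem cell and mesenchymal genes (10 of 20, -0.25, [0, 13], adjusted p = 0.0130, and adjusted p = 0.168 with an estimated correlation), with SNAI1 (-0.85 ± 0.11). Epithelial genes of this list, such as KRT8 (-0.72), were higher after BE-43547A1 too, so no shift toward mesenchymal genes follows. Glycolysis was higher (13 of 24, -0.16, [2, 18], adjusted p = 0.0228, and adjusted p = 0.238 with an estimated correlation), with PFKFB3 (-0.43 ± 0.07). Lower after BE-43547A1, against their lists, were HSD17B7, STARD4, GABARAPL1, WIPI1, ULK1, ABCG2, PGK1 and PDK1.

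Lists that did not differ by camera were mitochondrially encoded genes (2 higher and 1 lower after rakicidin A, [1, 2], adjusted p = 0.630), the tricarboxylic acid cycle (8 and 2, [5, 5], 0.146), mitochondrial dynamics (7 and 1, [4, 6], 0.167), HIF targets (15 and 4, [10, 6], 0.146) and NRF2 targets (3 and 8, [3, 10], 0.630). Nor did fatty acid synthesis (2 and 8, [1, 9], 0.162), p53 targets (6 and 6, median 0.056, mean -0.11, [3, 9], 0.5995), interferon (6 and 1, [5, 4], 0.0631) and histones (1 and 2, [1, 4], 0.475) differ. At most 1 of the mitochondrially encoded genes differed without rakicidin A replicate 3 or BE-43547A1 replicate 1. HIF targets passed without BE-43547A1 replicate 3 (0.0463), and interferon genes without DMSO replicate 2 (0.0407), rakicidin A replicate 2 (0.0401) or rakicidin A replicate 3 (0.0377). TNFRSF10B was higher after rakicidin A (0.54 ± 0.06) and TXNRD1 too (0.72 ± 0.06). CD14 (-2.49 ± 0.44) was lower after rakicidin A than after BE-43547A1, as was ITGAM (-0.53 ± 0.17) except without rakicidin A replicate 2 (-0.45, adjusted p = 0.0786) or BE-43547A1 replicate 1 (-0.41, 0.0827). Of the mitochondrially encoded genes MT-ND3 and MT-CO2 were higher and MT-ATP8 lower after rakicidin A, MT-ND3 not so without rakicidin A replicate 3 (0.60, adjusted p = 0.0523) or BE-43547A1 replicate 1 (0.57, 0.05998). The rarer differences upward were in GCLM, GCLC and TXNRD1, in ELOVL6 and MID1IP1 and in HIST1H1D. Those downward were in IDH2, in FKBP8, in ANGPTL4, FAM162A and WSB1, in IFITM1 and in HIST1H2BK and HIST1H2BD. With total counts alone MT-CO2, HSD17B7, ELOVL6, ABCG2 and MYC no longer differed by the test. With that scaling the medians of the tricarboxylic acid cycle (-0.016), HIF targets (-0.001) and p53 targets (-0.064) turned negative. Adjusted over the list alone, the counts were the same for every list except mitochondrially encoded genes (1 up, 1 down), mitochondrial ribosome (21 and 5), biogenesis (9 and 2) and dynamics (8 and 2), glycolysis (3 and 13), ATF4 (25 and 3), ER chaperones (22 and 0), heat shock (1 and 12), cholesterol synthesis (3 and 14), p53 targets (6 and 7), DNA replication (13 and 3), immediate early genes (3 and 17) and ribosome biogenesis (18 and 1).

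**Figure D2:**
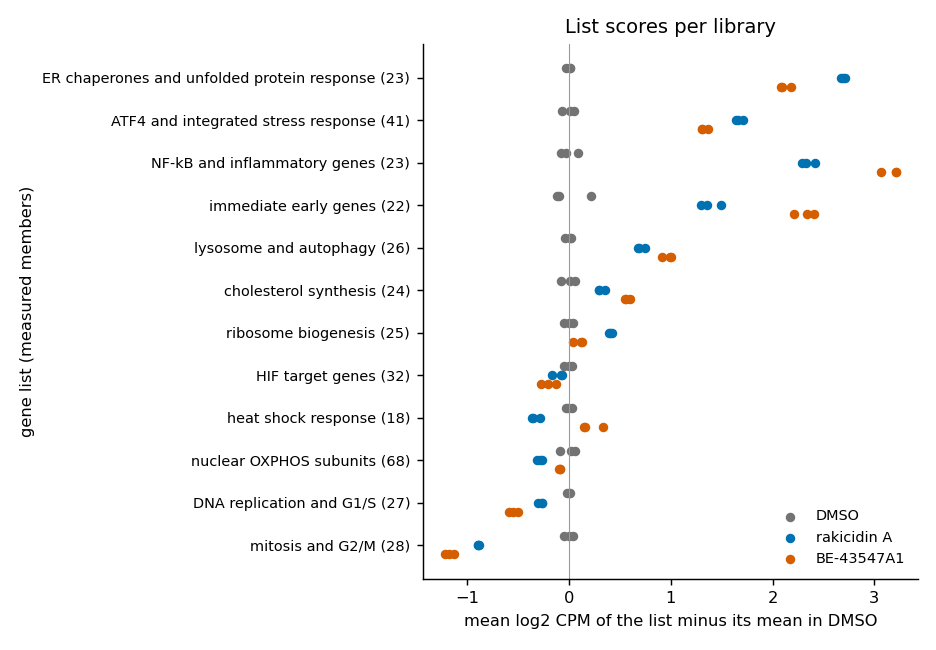
Points are the 9 libraries, coloured by group, with 12 gene lists on the y axis and on the x axis the mean log2 CPM of a list in the library minus its mean in DMSO. The NF-kB and immediate early lists are highest after BE-43547A1 and the ER chaperone list after rakicidin A, under TMM scaling.

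**Figure D3:**
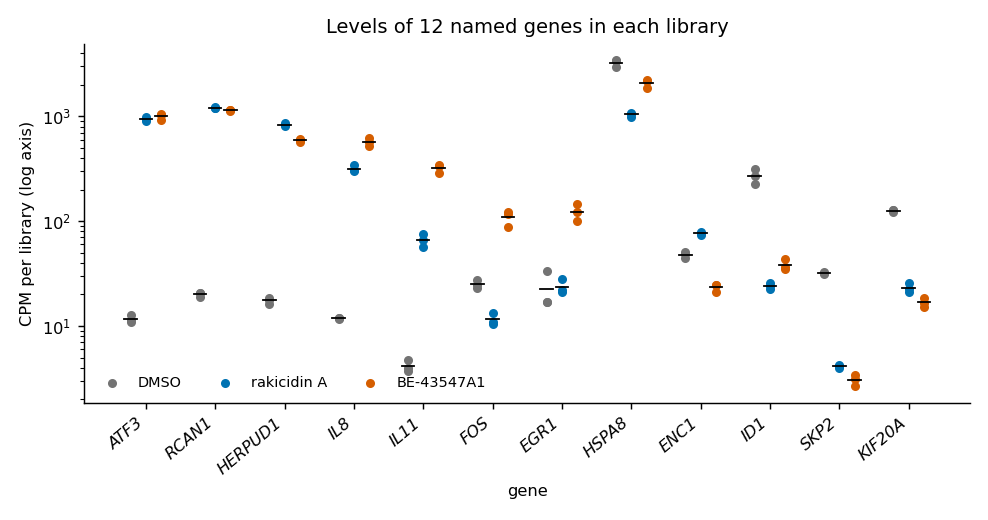
CPM per library on a log axis, scaled by TMM, for 12 named genes picked for display, with points for the 9 libraries by group and bars for the group means. ATF3, for example, lies at 11.7 CPM with DMSO and at 942.4 and 1007 CPM after the compounds.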

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

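The tests of scaling and of a common strength between the compounds were chosen only after the result was seen, and thinning was added after seeing the data but predicted before its value.

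A difference between groups drew attention to 573 genes that the compounds moved in opposite directions against DMSO, 412 higher after rakicidin A and lower after BE-43547A1 and 161 the reverse. With total counts alone there were 496, split 225 and 271, so the balance of the directions depends on the scaling, and over all alternatives there were 463 to 603. All 573 also passed the direct test, which opposite calls against the same DMSO libraries make nearly certain. Of the 573, 8 changed by at least 1 on the log2 scale after both compounds (5 to 10 over the alternatives). FOS (-3.23 between the compounds) and SCAND3 (2.14) were the 2 of these 8 among GENCODE genes with a mean CPM of at least 2, with clone names passed over. Other opposite changes, by the difference of rakicidin A and BE-43547A1, were in ENC1 (1.71), HSPA1A (-1.97), IFIT2 (1.30) and KRT8 (-0.72).

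ENC1 went from 47.8 ± 3.08 CPM with DMSO to 76.4 ± 2.54 CPM after rakicidin A and 23.4 ± 2.07 CPM after BE-43547A1, and IFIT2 from 23.8 ± 2.48 to 46.1 ± 4.42 and 18.7 ± 0.226 CPM. HSPA1A went from 79.8 ± 5.51 to 30.2 ± 2.94 and 119 ± 18.1 CPM, with reads that its near copy HSPA1B may share. KRT8, a keratin of simple epithelia, went from 900.2 ± 11.1 to 749 ± 18.8 and 1232 ± 59.1 CPM. Among the other list members, picked after their values were seen, JUNB (-0.30 after rakicidin A, 1.29 after BE-43547A1), ZFP36 (-0.41, 1.22), HSPA6 (-0.93, 1.47), INSIG1 (-0.27, 0.95) and GAPDH (-0.25, 0.34) fell and rose in that order, while FEN1 (0.31, -0.68) and MIEF1 (0.53, -0.48) rose and fell. Of these, HSPA6 had a low count, with a mean CPM under 2. With total counts alone FEN1 was at -0.051 after rakicidin A and GAPDH at 0.106 after BE-43547A1, neither passing, so these 2 were no longer opposite.

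The compounds differed in opposite directions between the ER chaperone list, higher after rakicidin A, and the immediate early and NF-kB lists, higher after BE-43547A1. None of these 3 camera calls held with an estimated correlation (adjusted p = 0.166, 0.168 and 0.166). The median difference of the ER list lay 1.341 above that of the immediate early list on the log2 scale, a restatement of the medians already seen, and 1 scaling factor, which shifts both lists alike, leaves no such gap. After all libraries were thinned to 1 depth this gap was 1.339. Thinning lowers counts but leaves the expected ratio between libraries as it was, so the value was nearly fixed and decides nothing about depth. The ratio of the ER score to the immediate early score was 1.95 ± 0.153 (SD, n = 3) after rakicidin A and 0.915 ± 0.0638 after BE-43547A1, a quotient of 0.469 that also restates the opposite directions. The compounds may weigh these responses differently, or may have reached different stages of a shared response at 12 h, which a single time and dose leave open.

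Splits of the 6 libraries of each comparison into other groups of 3 were counted too. The 10 splits of a comparison are too few for a share under 0.05. The real split gave 14455, 15738 and 10423 genes and the highest other split 0, 1 and 0 (1 of 10 splits reached the real count in each comparison, the real one itself).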

How the results depend on the processing

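Counts of passing genes stayed within 1.5 times the reported ones under every alternative except a log2 fold change of at least 1, which by its construction left 6211 for rakicidin A, 7075 for BE-43547A1, 2167 for the direct test and 4687 for both compounds in the same direction. With each library left out in turn the counts were 13611 to 14832, 15110 to 16454, 8878 to 11456 and 10893 to 11596. Other alternatives gave 13610 (DESeq2) to 15860 (total counts alone) for rakicidin A, 15578 (6 libraries) to 18734 (no filter) for BE-43547A1 and 8922 (DESeq2) to 11336 (6 libraries) for the direct test. Limma-voom gave 14286, 15804 and 10325. DESeq2 gave no adjusted p for 33722, 32373 and 41814 features. Thinning, added after seeing the data, gave 13946, 14845 and 9693, which shows what depth limits.

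The correlation between the compounds was 0.869, 0.648 without a filter, where more low-count genes are tested, 0.880 with a mean CPM of at least 2, and 0.843 to 0.875 with 1 library left out. The cause of the last range was not tested.

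Lists passing numbered 11, 10 and 18 as reported, 3, 6 and 0 with an estimated correlation and 22, 24 and 23 by fry, which tests another question. With 1 library left out they numbered 10 to 13, 10 to 11 and 18 to 19. Fry gave the opposite direction to camera after rakicidin A for the tricarboxylic acid cycle (median -0.041), HIF targets (0.23), fatty acid synthesis (-0.12) and stem cell genes (-0.043), where camera did not pass. Leaving out 1 library changed the camera direction for HIF targets (medians 0.22 to 0.30), fatty acid synthesis (-0.17 to -0.074) and stem cell genes (-0.047 to 0.078) after rakicidin A, and for mitochondrially encoded genes between the compounds (-0.18 to -0.001). The cause was not tested.

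Whether the replicate numbers pair the libraries is not stated in the labels, and the values here show no steady pairing without excluding it. After each group's mean log CPM was subtracted (genes with a mean CPM of at least 2), same-number libraries correlated at -0.15 to 0.25. Of these correlations of the remainders, 2 of 9 were over 0.1, and the own number was the best match in 3 of 9. With the replicate number as a block 14359, 15670 and 10347 genes passed, and the heat shock list after rakicidin A reached adjusted p = 0.0416.

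Of 147 named genes, 141, 143 and 100 passed in the 3 comparisons. At least 1 alternative lost the call for 12 after rakicidin A (MT-ND3, MT-CO3, MT-ND6, IDH3G, FASN, SNAI1, RPL28, RPS9, RPL12, HIST1H2BK, HIST1H2BD and THY1), 4 after BE-43547A1 (MT-CO3, MT-ND6, IFIH1 and COL3A1) and 16 between the compounds (HOXB8, KLHL14, MT-ND3, CYCS, DLD, MRPL15, KDM3A, SESN2, XBP1, AEN, TOP2A, SOD2, MCL1, CXCR4, ITGAM and THY1).

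Total counts alone, which shift all values downward by construction, changed the sign after rakicidin A of EGR1 (-0.27), IDH3G (-0.025), FASN (-0.069), RPS9 (-0.12), RPL12 (-0.084), ITGAM (-0.21) and ACTA2 (-0.29), and after BE-43547A1 of MID1IP1 (-0.16) and IFIH1 (-0.047). Between the compounds they did so for KRTAP2-3 (-0.063), RCAN1 (-0.035), PC (-0.098), SPG7 (-0.058), PPFIA4 (-0.085), HK2 (-0.12), PPP1R15A (-0.043), LPIN1 (-0.005), MAP1LC3B (-0.099), BBC3 (-0.011), DUSP1 (-0.022), PMAIP1 (-0.074), RRP12 (-0.068), HIST2H2BE (-0.089) and ACTA2 (-0.004).

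Signs of genes near 0 also changed elsewhere, and the cause was not tested. Without a filter PC was at -0.003, HK2 at -0.022 and MAP1LC3B at -0.004 between the compounds. Thinned, ITGAM was at -0.032 after rakicidin A, and HILPDA (0.011), HK2 (-0.007) and COL3A1 (-0.069) turned between the compounds. The 6 libraries alone put HK2 at -0.002, RLE put HSPA4L at 0, and DESeq2 put HILPDA at 0.014, HSPA4L at 0.017, GADD45A at 0.01, RRM2 at 0.008 and ZEB1 at 0.011.

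With 1 library left out the sign changed, for an untested cause, after rakicidin A for EGR1 (-0.075 to 0.50), RPL24 (-0.11 to 0.053), CD14 (-0.67 to 0.20) and ACTA2 (-0.17 to 0.33), and after BE-43547A1 for MID1IP1 (-0.001 to 0.15), THY1 (-0.13 to 0.026) and ACTA2 (-0.19 to 0.16). Between the compounds it did so for KRTAP2-3 (-0.10 to 0.22), MT-ND4 (-0.12 to 0.13), PC (-0.001 to 0.05), HILPDA (-0.08 to 0.042), HK2 (-0.033 to 0.04), HSPA4L (-0.045 to 0.027), PNPLA3 (-0.18 to 0.087), MAP1LC3B (-0.02 to 0.07), GADD45A (-0.045 to 0.009), BBC3 (-0.032 to 0.20), RRM2 (-0.041 to 0.018), SAMD9 (-0.071 to 0.055), ZEB1 (-0.069 to 0.026), COL3A1 (-0.001 to 0.24) and ACTA2 (-0.13 to 0.37).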

Other observations

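The lists of this part and the tests of scaling and of other transcription factor families were chosen only after the result was seen. Camera p-values of these added lists were adjusted over the added lists alone, a milder adjustment than over the 27 fixed lists.

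Ligands of the EGF receptor family rose after both compounds, 3 of 4 measured, too few to test as a list. HBEGF rose from 9.18 ± 0.850 CPM with DMSO to 198 ± 7.76 after rakicidin A and 127 ± 5.63 after BE-43547A1 (mean ± SD, n = 3), EREG from 8.36 to 50.9 and 37.4 CPM and NRG1 from 25.6 to 122 and 87.7 CPM, while TGFA fell by 0.53 on the log2 scale after BE-43547A1 and did not pass after rakicidin A (-0.19, edgeR adjusted p = 0.217). Dual-specificity phosphatases, which switch off MAP kinases, rose in 8 of 10 cases after each compound (camera adjusted p = 4.96e-13 and 2.62e-12, and 0.00626 and 0.00544 with an estimated correlation). DUSP16 rose from 9.02 to 56.6 and 79.2 CPM and DUSP10 from 1.85 to 8.96 and 8.64 CPM, and DUSP2 (-1.99 and -1.04) and DUSP9 (-0.70 and -0.55) fell. Some members of this list had already been seen among the largest changes.

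Feedback genes of BMP and SMAD signalling fell in 6 of 8 cases after each compound (camera adjusted p = 3.63e-05 and 0.00245, but 0.138 and 0.197 with an estimated correlation). The member ID1 (-3.48 and -2.82) had already been seen among the largest falls after rakicidin A, so this list was not independent of them. ID2 fell from 60.1 to 16.6 and 31.1 CPM and SMAD6 from 24.9 to 8.55 and 8.03 CPM, and SMAD7 and BAMBI rose after BE-43547A1. Proteasome subunits rose in 16 and fell in 3 of 31 cases after rakicidin A and rose in 11 and fell in 5 after BE-43547A1 without passing (camera adjusted p = 0.428 and 0.831). Their medians were small (0.17 and 0.092), so the sign of these changes is relative to the TMM scaling.

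Transcripts of the MiTranscriptome catalogue were lower after rakicidin A than after BE-43547A1 in 1354 of 4146 cases and higher in 260, while GENCODE genes were lower in 3672 and higher in 5119 of 18122. Against DMSO 1854 were higher and 1059 lower after BE-43547A1, and 1197 and 1184 after rakicidin A. Thinned to 1 depth, a step added after seeing this, 1178 of 3754 were lower and 198 higher between the compounds. Thinning leaves the expected ratio between libraries as it was, so this direction was nearly fixed. The counts by catalogue were made under TMM only.

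Genes named ZNF with a number, most of which encode zinc finger transcription factors, fell in 302 and rose in 91 of 455 cases after BE-43547A1 (median -0.65, camera adjusted p = 9.54e-10, and 0.172 with an estimated correlation), against 193 and 160 after rakicidin A (median -0.064). Between the compounds 308 were higher and 21 lower after rakicidin A (median 0.49, camera adjusted p = 1.06e-23, and 0.0474 with an estimated correlation). The members ZNF737 and ZNF681 had already been seen among the largest falls after BE-43547A1, so this list was not independent of them. The median relative to all genes was -0.646, which restates the observation and which 1 scaling factor, moving all genes alike, leaves at 0. Other transcription factor families lay 0.68 higher (difference -0.676). With the trend on transcript length, GC content and expression removed (R squared 0.0380) the difference was -0.355, between the bounds written beforehand for and against that explanation, so it stays open. The lowest median of 10000 random lists matched on expression was -0.251. Those lists were not matched on length, GC content or the correlation between ZNF genes (estimated at 0.096), so they do not show how unusual the ZNF median is. The cause was not tested further.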
